A study of Mus musculus with 6 samples.

How the data were processed

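The data were RNA-seq gene counts of microglia, the resident macrophages of the brain, isolated from the brains of mice on a mixed B6;129S4 background. Hexb-KO/KO animals carry a knockout allele on both chromosomes, and Hexb-KO/wt animals carry 1 wild-type allele. Groups were taken from the genotype given for each sample, with 3 libraries per group. Replicate numbers only name the libraries and do not pair them. The labels do not state the age or sex of the mice or how the cells were gated. They also do not say that each library came from a separate animal, so p-values measure the spread between these samples only.

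Per the labels' protocols, RNA was purified from stabilised cells, and 500 pg of total RNA entered a SMARTer low-input cDNA synthesis with 12 cycles of cDNA amplification. Nextera XT tagmentation then gave libraries that were read as single reads of 50 bases. This kit does not mark the strand of the RNA. Amplified reads without molecular identifiers are not independent molecules, so all counting intervals and floors given here cover counting error only.

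The authors deposited whole-number read counts per gene, with no normalization, in 1 table. Per the submitters' processing notes, the tools were STAR 2.7.2a, featureCounts 1.6.2 and limma, the last with no stated role, and the genome build was GRCm38.p6. Per the file headers, each row gives a gene symbol with its exon coordinates, strand and exon length. The strand setting, the treatment of multi-mapping reads and the annotation release are not given in the sources used here. The genes mt-Co2, mt-Atp6, mt-Atp8 and Jund had 0 counts in all 6 libraries, and the reason was not tested. Since the treatment of multi-mapping reads is unknown, levels of mitochondrial genes and of families with similar sequences, such as ribosomal proteins, ferritins and H2 genes, are uncertain. Reads of genes whose exons overlap on opposite strands cannot be told apart either, as for Hexb and Gfm2, Irf7 and Phrf1, Ctsz and Nelfcd, Cox4i1 and Emc8, Rpl32 and Cand2, Cnp and Dnajc7, and Il1b and Il1bos.

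The table held 55341 genes. Library totals ran from 16946831 to 29721686 counts, so that 1 count corresponded to 0.0336 to 0.059 CPM, the count scaled to the library total. Within a group, pairs of libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 55.6 to 121 over genes with at least 50 counts in the pair, so no library was a copy of another. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (a minimum count of 10) were kept, libraries were scaled by TMM, and KO/KO was compared with KO/wt by the quasi-likelihood F-test (glmQLFit and glmQLFTest). P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. No covariate was used. Levels are TMM-scaled CPM as mean ± SD over 3 libraries, and log2 fold changes are KO/KO minus KO/wt with an approximate standard error (SE). The test reports no SE, so it was taken as the absolute log2 fold change divided by the square root of the F statistic. For a gene with 1 to 3 counts in all KO/wt libraries together, the ratio of count shares is given with its 95% exact counting interval. With 0 counts, a lower bound against a floor of 3 counts over the whole group is given. Fitted fold changes of such genes depend on the prior count.

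Before the data were examined, 27 gene lists were fixed from general knowledge: 16 for microglial states and cell functions, 10 for other cell types, and 1 for Xist and Y-linked genes. The lists were not chosen on these samples. Lists with at least 3 tested members were compared with all other genes by camera from limma 3.58.1, with a preset correlation of 0.01 between genes, and adjusted over the lists. Camera with a correlation estimated from the data and fry were run beside it. Hexb was left out of its own list. The share of called genes within 10 Mb of Hexb was compared with that of all other genes by a two-sided Fisher's exact test, since a knockout allele on a mixed background can bring flanking DNA of the other strain.

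The genes named were also fixed by a rule. It took Hexb, Hexa and Gm2a, and the 12 genes per direction with the largest log2 fold change among called genes with a mean of at least 5 CPM, no overlap between the groups and a proper gene name. It also took up to 4 members per list, called ones by size first and then the uncalled ones of highest CPM. P2ry12, Cx3cr1, Axl, Cst7, Clec7a, Gfm2, Cst3, Siglech, Sparc, Ltc4s and the members of lists described only in the closing section were added after their values were seen.

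The alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, library totals, no low-count filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test with its own filtering, limma-voom with and without quality weights, a minimum fold of 2, other windows around Hexb, and leaving out each library in turn. Offsets that remove a gene length trend from each library were added after seeing the data. The tests were tested on simulated data. On counts with the means and spread of the KO/KO against KO/wt comparison, the edgeR test recovered 3% of the genes changed 2-fold and 45% of those changed 4-fold, and 5.88% of its calls were false, over 11820 genes. On the same simulation DESeq2 recovered 13% and 64%, with 38.9% of its calls false, over 12456 genes. This was a single simulated data set, with 100 genes changed by each fold and genes drawn independently of each other. It gave 51 edgeR calls, against 462 in the data, so its rates need not hold for the data. Small changes can still have been missed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.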

Results

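Microglial RNA from the brains of Hexb-KO/KO and Hexb-KO/wt mice was sequenced in 3 libraries per genotype. Hexb encodes the beta subunit of lysosomal beta-hexosaminidase, which removes a terminal sugar from GM2 ganglioside, and it is one of the genes that mark microglia most strongly. The single comparison that the genotypes imply asks what differs in microglia when the second Hexb allele is also lost, with the heterozygotes as the only control. The KO/KO libraries held 20413862, 25782284 and 22253753 counts, and the KO/wt libraries 29721686, 25917410 and 16946831. Between 15564 and 20861 genes had at least 1 count in a library. The 10 most abundant genes took 14.2% to 19.4% of the counts. The correlation of log2 CPM was 0.828 to 0.915 between libraries of 1 genotype and 0.793 to 0.868 across genotypes. By this correlation KO/KO replicate 3 was as close to the KO/wt libraries (0.856, 0.86 and 0.868) as to KO/KO replicates 1 and 2 (0.858 and 0.856). By chi-square per degree of freedom it lay closer to KO/KO replicates 1 and 2 (95.2 and 121) than to the KO/wt libraries (305, 285 and 247). All 6 libraries expressed the Y-linked genes Ddx3y (41.6 to 70 CPM) and Eif2s3y (39.5 to 80.4 CPM), while Xist stayed at or under 0.245 CPM.

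Hexb RNA was strongly reduced in KO/KO microglia, to 708 ± 84.5 CPM (SD, n = 3) from 11720 ± 1162 CPM (n = 3) in KO/wt microglia, or 6.04% of the heterozygous level. Every KO/KO library lay below every KO/wt library, so the genotype labels and the target gene went together in all 6 libraries. The log2 fold change was −4.05 (SE 0.138, adjusted p = 3.58e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hexb lies on chromosome 13 at 97176331 to 97198357 of GRCm38, on the minus strand, and the count covers all its exons together, so the residual reads were not assigned to an exon. Gm2a, the activator protein that presents GM2 ganglioside to the enzyme, rose from 396 ± 42.0 to 714 ± 39.5 CPM, a log2 fold change of 0.85 (SE 0.13, adjusted p = 0.0165). Hexa, the alpha subunit of the same enzyme, measured 2395 ± 307 CPM in KO/KO and 1785 ± 116 CPM in KO/wt, and did not pass the test (log2 fold change 0.42, adjusted p = 0.117). The call of Gm2a was lost in 4 of the 6 fits that left out 1 library, with the highest adjusted p, 0.0986, without KO/wt replicate 2.

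The 12 genes with the largest increase in KO/KO microglia included complement C3, the secreted phosphoprotein osteopontin (Spp1), the chemokine Cxcl13 and the matrix proteins fibronectin (Fn1) and Emilin2. Spp1 rose from 2.14 ± 1.79 to 2611 ± 628 CPM (log2 fold change 10.21, SE 0.691), and Cxcl13 from 5.85 ± 3.12 to 1791 ± 888 CPM (8.28, SE 0.577). C3 was nearly absent from KO/wt microglia, with 1 count in the 3 libraries together, against 2924 counts in KO/KO, a ratio of 3100 (95% counting interval 556 to 123000). Count ratios were also taken for Emilin2 (ratio 2230, 399 to 88000), the adhesion receptor Adgrg5 (1100, 306 to 9130), the adaptor Bcar3 (723, 200 to 5980), Ms4a4a (745, 133 to 29500), the inhibitory lectin receptor Clec12a (441, 122 to 3650) and the integrin subunit Itgal (265, 90.2 to 1290). Fn1 (log2 fold change 8.38, SE 1.07), Ms4a7 (7.88, SE 0.978) and the secreted glutathione peroxidase Gpx3 (7.87, SE 1.01) were the others of the 12. Single KO/wt libraries set some of these values: without KO/wt replicate 1 Ms4a7 measured 10.9 and Spp1 11.2, without KO/wt replicate 2 Gpx3 measured 11.2, and without KO/wt replicate 3 Fn1 measured 9.61. The lowest log2 fold change of Fn1 with 1 library left out was 7.64. Fn1 was not called by limma-voom (adjusted p = 0.275, or 0.161 with quality weights).

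The 12 genes with the largest decrease included Hexb. Sema6d, a transmembrane semaphorin, fell from 12.5 ± 3.72 to 0.0643 ± 0.0783 CPM (log2 fold change −7.53, SE 1.14), and Ccdc162 from 10.2 ± 11.3 to 0.0638 ± 0.0555 CPM (−7.24, SE 1.44). The orphan receptor Gpr165 (−3.69, SE 0.557), Nhsl2 (−2.93, SE 0.625), Irgq (−2.74, SE 0.412), Serpinf1 (−2.55, SE 0.543) and Il7r, a subunit of the interleukin-7 receptor (−2.11, SE 0.304), fell as well. So did the integrin subunit Itga9 (−2.10, SE 0.347), the tight junction protein Tjp1 (−1.91, SE 0.285), the Myc family member Mycl (−1.87, SE 0.351) and Btbd3 (−1.82, SE 0.39). Adjusted p of these 11 genes ran from 0.0133 for Il7r to 0.0487 for Btbd3. Each of the 11 lost its call in at least 1 fit with a library left out. Ccdc162 and Btbd3 lost it in all 6, with the highest adjusted p at 0.136 without KO/wt replicate 1 and 0.211 without KO/wt replicate 2. Il7r lost it in 1, without KO/wt replicate 3 (adjusted p = 0.0664). Serpinf1 had 774 CPM in KO/wt replicate 3, and its log2 fold change was −1.60 without that library. Without KO/wt replicate 1 Ccdc162 measured −5.77, and without KO/wt replicate 3 Gpr165 measured −3.02, while without KO/KO replicates 1 and 3 Sema6d and Nhsl2 measured −8.89 and −3.63. In limma-voom without and with quality weights Ccdc162 (0.205 and 0.226), Serpinf1 (0.0897 and 0.109) and Gpr165 (0.051 and 0.0636) were not called, and with gene length offsets Btbd3 (0.0633) was not.

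In all, 462 of 12456 tested genes were called, 332 higher and 130 lower in KO/KO, so that 71.9% of the calls were increases. When libraries were scaled by their totals alone, 293 genes were higher and 183 lower, and the share of increases was 61.6%. The groups did not overlap for any of the 462 called genes, as was the case for 26.8% of all tested genes, where chance gives 10%. The number of calls depended on the libraries: 124 without KO/KO replicate 1, 139 without replicate 2 and 337 without replicate 3, and 309, 126 and 132 without KO/wt replicates 1, 2 and 3. Of the 462 calls, 120 (without KO/wt replicate 3) to 254 (without KO/KO replicate 3) were kept in these fits. Losing a call there was therefore common among called genes, with fewer samples in each fit. Of 26 gene lists tested by camera, 19 passed, 18 upward and 1 downward. With a correlation estimated from the data 6 passed: homeostatic microglia downward, and disease-associated microglia, interferon response, MHC and antigen presentation, cytokines and chemokines, and lysosome upward. By fry, which tests each list without comparing it with other genes, 22 passed: the same 19 and glycosphingolipid metabolism, lymphocytes, and endothelium and mural cells.

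**Figure D1:**
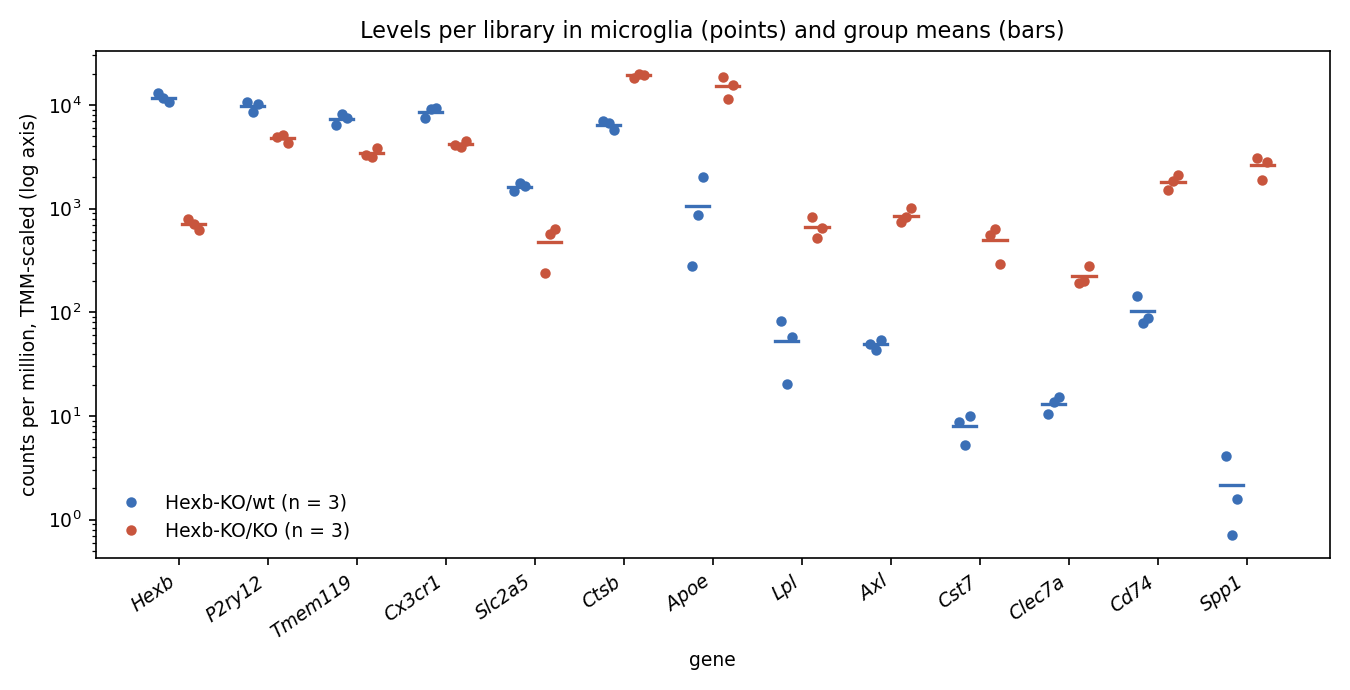
TMM-scaled CPM of 13 genes in each library, on a log axis, with KO/wt libraries in blue, KO/KO libraries in red and bars at the group means of 3 libraries. Hexb and the homeostatic genes P2ry12, Tmem119, Cx3cr1 and Slc2a5 lie lower in KO/KO, and the other 8 genes lie higher, with no overlap between the groups in any of the 13.

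Genes of homeostatic microglia, which mark the resting state, were in part lower in KO/KO, with a list median of −0.80 in log2 fold change. The fructose transporter gene Slc2a5 fell from 1630 ± 150 to 478 ± 209 CPM (log2 fold change −1.77, SE 0.328), Selplg from 8209 ± 495 to 3727 ± 192 CPM (−1.14, SE 0.0934), the chemokine receptor Ccr5 from 1148 ± 60.4 to 531 ± 66.2 CPM (−1.11, SE 0.133) and Tmem119 from 7307 ± 870 to 3423 ± 370 CPM (−1.09, SE 0.126). The purinergic receptor P2ry12 and the fractalkine receptor Cx3cr1 fell by 1.04 (SE 0.123) and 1.05 (SE 0.114) on the log2 scale. Of the 25 members other than Hexb, 13 fell, and 18 fell when adjusted over the list alone. Among the 12 that were not called were Cst3 (−0.08), Siglech and Sparc (−0.16 each) and Ltc4s (0.16). With gene length offsets Cst3 and Ltc4s measured −0.57 and −0.44. Tested markers of other cells had medians above 0 at the same time. These were 2.48 for border-associated macrophages, 1.91 for monocytes, 3.99 for choroid plexus and 1.43 for astrocytes. Few of these markers were called, and the only called gene of the astrocyte list fell. None of these marker lists passed camera with an estimated correlation. The homeostatic list passed camera (adjusted p = 2.41e-18, and adjusted p = 0.00497 with an estimated correlation). Leaving out 1 library left 8 to 11 members called, and the call of Slc2a5 was lost in 4 of these fits (highest adjusted p = 0.129, without KO/wt replicate 2).

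Genes of disease-associated microglia, a state described around amyloid plaques and in other brain disease, rose together. Of 43 tested members 36 rose, and 40 when adjusted over the list alone. Spp1, described above, was followed by Gpnmb (1.03 ± 1.66 to 156 ± 61.1 CPM, log2 fold change 7.19, SE 1.19), the heparanase gene Hpse (0.573 ± 0.814 to 53.9 ± 20.8 CPM, 6.67, SE 1.06) and Ch25h, which makes 25-hydroxycholesterol (0.894 ± 1.47 to 94.6 ± 15.2 CPM, 6.63, SE 1.18). The receptor tyrosine kinase Axl rose from 48.9 ± 5.58 to 856 ± 137 CPM (4.13, SE 0.183, adjusted p = 0.00014). The cystatin gene Cst7 reached 496 ± 178 CPM from 7.98 ± 2.5 CPM (5.96, SE 0.407), and the beta-glucan receptor gene Clec7a 225 ± 49.6 CPM from 13.1 ± 2.53 CPM (4.10, SE 0.253). The list passed camera (adjusted p = 6.98e-103, and adjusted p = 0.00153 with an estimated correlation). Border-associated macrophage and monocyte genes had medians of 2.48 and 1.91, with 2 of 14 and 2 of 10 called higher. With each library left out in turn, 23 to 37 members rose. Gpnmb, Hpse and Ch25h lost their calls in 4, 4 and 5 of those fits, with the highest adjusted p at 0.0834 without KO/wt replicate 3, 0.0664 without KO/wt replicate 2 and 0.0903 without KO/KO replicate 1. Most KO/wt reads of Gpnmb came from replicate 2, those of Ch25h from replicate 1 and those of Hpse from replicate 3, and without these libraries the log2 fold changes were 11.1, 10.9 and 8.93. In limma-voom Gpnmb (0.0692) and Hpse (0.0553) were not called.

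**Figure D2:**
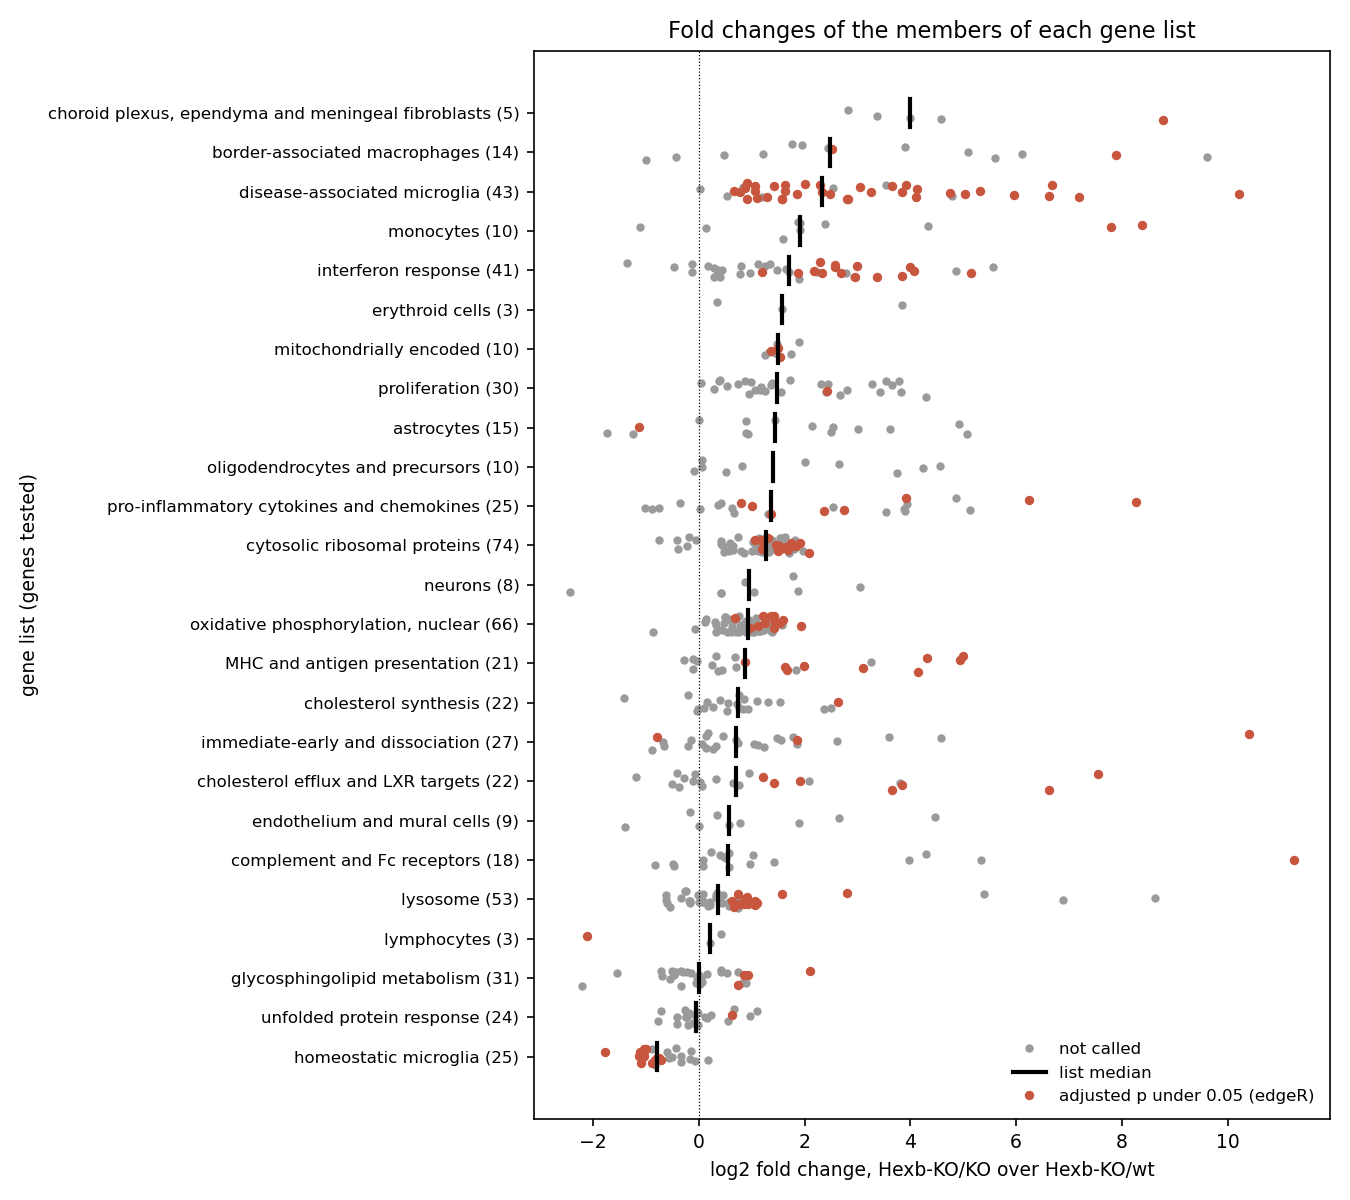
Log2 fold changes of the tested members of each gene list, KO/KO over KO/wt, with called members in red, other members in grey and the list median as a black bar; numbers in parentheses count the members tested. Genes with 0 counts in a group are drawn at their fitted value. The homeostatic list lies to the left of 0, with 13 of 25 members called, and the disease-associated list to the right, with 36 of 43.

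Lysosomal genes rose in part. Cathepsin B (Ctsb), one of the most abundant transcripts, rose from 6448 ± 679 to 19190 ± 873 CPM (log2 fold change 1.57, SE 0.102), and the tetraspanin gene Cd63 from 148 ± 27.3 to 1032 ± 106 CPM (2.80, SE 0.18). Cathepsins Z and L (Ctsz and Ctsl) rose by log2 fold changes of 1.11 (SE 0.111) and 1.06 (SE 0.156). Of 53 tested lysosomal genes 13 rose. Adjusted over the list alone, 23 rose and 2 fell. The list passed camera (adjusted p = 1.95e-10, and adjusted p = 0.0186 with an estimated correlation), and 5 to 11 members rose with 1 library left out. Ctsl lost its call without KO/KO replicate 1 (adjusted p = 0.0533) and without KO/KO replicate 2 (0.0593). Of the 13 called genes, Cd63, Ctsb, Ctsz, Ctsd, Cd68, Ctsa, Gusb and Ctsl also belong to the disease-associated list. Grn, Lamp1, Atp6v1b2, Naglu and Gaa do not.

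In glycosphingolipid metabolism, the pathway of the missing enzyme, single genes rose, and tests of the whole list differed. Besides Gm2a, these were alpha-galactosidase Gla (8.98 ± 3.72 to 38.4 ± 10 CPM, log2 fold change 2.09, SE 0.429), the GM2 and GD2 synthase B4galnt1 (0.93, SE 0.188) and the glucocerebrosidase gene Gba (0.73, SE 0.123). These were 4 of 31 tested genes, while 9 rose and 1 fell when adjusted over the list alone. The list did not pass camera (adjusted p = 0.157, and adjusted p = 0.223 with an estimated correlation), but it passed fry (adjusted p = 0.00858). Its median log2 fold change lay just below 0 while its mean and camera pointed up. Gla lost its call in all 6 fits with a library left out (highest adjusted p = 0.132, without KO/KO replicate 1). B4galnt1 and Gba lost it in 5 (0.153 and 0.121, both without KO/wt replicate 2), and B4galnt1 also with library totals alone (0.0513).

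Some genes of cholesterol efflux rose in KO/KO, where medians of border-associated macrophage (2.48), choroid plexus (3.99) and astrocyte (1.43) genes were also above 0. Few of those markers were called. Apolipoprotein E (Apoe) rose from 1062 ± 891 to 15160 ± 3512 CPM (log2 fold change 3.84, SE 0.653) and lipoprotein lipase (Lpl) from 53.1 ± 30.8 to 664 ± 149 CPM (3.64, SE 0.483), and Apoc4 had a count ratio of 239 (42.4 to 9470). Ch25h was also among the 7 of 22 genes of cholesterol efflux and LXR targets that rose. Of the 7, Apoe, Lpl, Npc2 and Ch25h also belong to the disease-associated list. Adjusted over the efflux list alone, 11 rose and 2 fell. Camera gave adjusted p = 4.84e-06, and adjusted p = 0.0561 with an estimated correlation. With 1 library left out, 2 to 5 of the 22 genes rose and at most 1 fell. In cholesterol synthesis Sqle, the squalene epoxidase gene, rose from 4.01 ± 1.08 to 24.7 ± 2.92 CPM (2.62, SE 0.415), the only called gene of 22 over all genes and over the list alone. Ebp (0.28, SE 0.221), Msmo1 (0.56, SE 0.213) and Cyp51 (0.75, SE 0.35) did not pass, and camera gave adjusted p = 0.00438, but adjusted p = 0.0869 with an estimated correlation. Calls lost with 1 library left out were those of Apoe (4 fits, highest adjusted p = 0.127 without KO/wt replicate 2), Apoc4 and Sqle (6 fits each, 0.162 and 0.0802, both without KO/wt replicate 3) and Lpl (1 fit, 0.0608 without KO/wt replicate 3). Without KO/wt replicate 3 the log2 fold change of Apoe was 4.72. Apoc4 was also not called by limma-voom (0.0516).

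Interferon-stimulated genes and antigen presentation genes rose in part. Rsad2, which encodes viperin, rose from 0.969 ± 0.614 to 35.1 ± 24.0 CPM (log2 fold change 5.14, SE 0.845), and Ifitm3 (4.07, SE 0.333), Ifi27l2a (4.0, SE 0.543) and the transcription factor Irf7 (3.84, SE 0.465) rose as well. In this list 15 of 41 genes rose, and 23 when adjusted over the list alone (camera adjusted p = 2.2e-20, and 0.00497 as an adjusted p with an estimated correlation). The MHC class II genes H2-Aa (11.9 ± 12.1 to 386 ± 63.3 CPM, 5.00, SE 0.707), H2-Eb1 (4.94, SE 0.813) and H2-Ab1 (4.31, SE 0.559) rose with the invariant chain Cd74, from 103 ± 34.1 to 1819 ± 305 CPM (4.14, SE 0.27). Markers of other cells that bear MHC class II also had median log2 fold changes above 0. The median was 2.48 in border-associated macrophage genes (12 of 14 above 0, 2 called) and 1.91 in monocyte genes (9 of 10 above 0, 2 called). Of 21 presentation genes 9 rose, and 11 when adjusted over the list alone (camera adjusted p = 4.61e-19, and 0.0108 as an adjusted p with an estimated correlation). With 1 library left out, 4 to 9 interferon and 5 to 8 presentation genes rose. Rsad2 lost its call in 5 of these fits (highest adjusted p = 0.102, without KO/wt replicate 2) and H2-Eb1 in 4 (0.104, without KO/wt replicate 3), while Ifi27l2a (0.066) and H2-Aa (0.059) lost it without KO/wt replicate 3. Without KO/wt replicate 1 the log2 fold changes of H2-Aa, H2-Eb1 and H2-Ab1 were 6.28, 6.32 and 5.21, and without KO/KO replicate 1 that of Rsad2 was 4.55. Rsad2 was also not called by limma-voom (0.168, or 0.0806 with quality weights).

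Cytokine and chemokine genes rose in part. Beside Cxcl13, these included Cxcl14 (0.684 ± 0.0921 to 52.1 ± 12.1 CPM, log2 fold change 6.25, SE 0.372), the macrophage inflammatory protein gene Ccl3 (18.6 ± 18.6 to 283 ± 78.9 CPM, 3.92, SE 0.78) and Il1b (8.29 ± 0.663 to 55.9 ± 43.7 CPM, 2.75, SE 0.579). Of 25 tested genes 8 rose, and 15 when adjusted over the list alone (camera adjusted p = 2.44e-16, and 0.008 as an adjusted p with an estimated correlation). Between 4 and 7 rose with 1 library left out, and Ccl3 and Il1b lost their calls in 4 and 5 of those fits (highest adjusted p 0.175 and 0.179, both without KO/wt replicate 2). The log2 fold change of Ccl3 was 5.08 without KO/wt replicate 1, and that of Il1b was 1.92 without KO/KO replicate 1. Il1b also missed the threshold with library totals alone, with gene length offsets and in both limma-voom fits. Monocyte and border-associated macrophage genes had medians of 1.91 and 2.48 in log2 fold change, with 2 of 10 and 2 of 14 called higher. Among complement and Fc receptor genes, C3 was the only 1 of 18 called. The abundant C1q chains C1qb (18080 ± 2717 against 12130 ± 1519 CPM, 0.58, SE 0.137), C1qc (0.48, SE 0.119) and C1qa (0.52, SE 0.129) did not pass over all genes (adjusted p = 0.0661, 0.0743 and 0.0759). All 3 passed with no low-count filter, with a mean of at least 5 CPM, with DESeq2 and in both limma-voom fits, and C1qa also without KO/KO replicate 3 (0.0398). With gene length offsets they measured 0.01, 0.19 and −0.08. DESeq2 called 9 genes of this list and limma-voom 6. Adjusted over the list alone, 10 rose and 1 fell. Camera gave adjusted p = 1.21e-05 for this list, and adjusted p = 0.06 with an estimated correlation.

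Proliferation genes all had a log2 fold change above 0, 30 of 30 with a median of 1.47, although Mcm3 reversed with library totals alone, and few passed the test. Cdk1, a kinase that drives entry into mitosis, rose from 6.70 ± 1.09 to 35.7 ± 14.2 CPM (log2 fold change 2.42, SE 0.392) as 1 of 30 proliferation genes, or 2 when adjusted over the list alone, 7 by DESeq2 and 2 by limma-voom. Mcm4 (1.56, SE 0.363), Rrm1 (0.39, SE 0.283) and Mcm3 (0.05, SE 0.397) did not pass. Camera gave this list adjusted p = 1.77e-07, but adjusted p = 0.223 with an estimated correlation. Among 27 immediate-early and dissociation genes, Gadd45b was at least 172-fold higher (488 counts against 0), Atf3 rose (1.85, SE 0.265), Btg2 fell (−0.79, SE 0.157) and Dusp6 did not pass (−0.69, SE 0.174). Adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.0223, and 0.223 as an adjusted p with an estimated correlation). In the unfolded protein response Sdf2l1 rose (0.62, SE 0.129), 1 of 24 genes over all genes and over the list alone, and the chaperones Pdia3 (−0.26, SE 0.0969), Hspa5 (−0.20, SE 0.166) and Calr (0.16, SE 0.12) did not pass. That list did not pass camera (adjusted p = 0.861, and 0.908 with an estimated correlation), its median and test pointing down and its mean up. Sdf2l1 was not called with library totals alone (0.0648) or with no low-count filter (0.0502), and with gene length offsets its log2 fold change was 0.07 (adjusted p = 0.869). Sdf2l1 and Btg2 lost their calls in all 6 fits with a library left out (highest adjusted p 0.193 and 0.165), Cdk1 and Gadd45b in 4 (0.101 and 0.0853) and Atf3 in 2 (0.0764), with all of these values without KO/wt replicate 2 except that of Gadd45b, without KO/KO replicate 2.

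Genes of mitochondrial respiration and of the ribosome mostly had log2 fold changes above 0 in KO/KO, but only part of them passed the test. Of 66 nuclear genes of oxidative phosphorylation 12 rose, and 48 when adjusted over the list alone. Examples were Ndufa1 (21.6 ± 5.92 to 82.4 ± 24.7 CPM, log2 fold change 1.93, SE 0.317), Cox4i1 (1.59, SE 0.234), Atp5e (1.54, SE 0.328) and Uqcrq (1.45, SE 0.246). Of 10 mitochondrially encoded genes mt-Nd1 (1.53, SE 0.288), mt-Co1 (1.5, SE 0.243) and mt-Cytb (1.37, SE 0.278) rose, the ribosomal RNA mt-Rnr2 did not pass (1.74, SE 0.403), and 9 rose when adjusted over the list alone. Of 74 cytosolic ribosomal protein genes 16 rose, and 34 when adjusted over the list alone, led by Rpl32 (44.2 ± 9.61 to 188 ± 40.3 CPM, 2.08, SE 0.244), Rps20 (1.92, SE 0.307), Rps19 (1.84, SE 0.276) and Rpl37a (1.74, SE 0.359). The share of mitochondrially encoded counts was 0.695%, 0.604% and 0.371% in the KO/KO libraries and 0.292%, 0.177% and 0.168% in the KO/wt libraries. This share holds almost nothing from mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l, which had at most 4 counts each over all 6 libraries. Camera passed these 3 lists (adjusted p = 7.24e-23, 1.65e-10 and 3.43e-18), but with an estimated correlation their adjusted p was 0.185, 0.181 and 0.185. Over all genes the median log2 fold change went from 0.27 to −0.22 between the shortest and the longest of 4 equal groups by exon length. With gene length offsets 6, 2 and 11 genes were called, and with library totals alone 8, 3 and 15. Atp5e (0.0586), mt-Cytb (0.0621) and Rpl37a (0.0724) lost their calls with the offsets, Atp5e with library totals (0.0519) and Rpl37a with limma-voom (0.0508). With 1 library left out the counts of called genes ran from 0 to 13, 0 to 6 and 1 to 18, and of the genes named here only Rpl32 was called in all 6 such fits. The highest adjusted p of the others lay between 0.0896 for Rps19 and Cox4i1 and 0.194 for Atp5e, these 3 without KO/wt replicate 2.

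Markers of several other cells were higher in KO/KO, although few passed the test. The median log2 fold change was 2.48 for border-associated macrophages, 1.91 for monocytes and 3.99 for choroid plexus. Among border-associated macrophage markers, Dab2 rose from 18.7 ± 5.29 to 107 ± 12.4 CPM (log2 fold change 2.52, SE 0.269) and Ms4a7 from 0.207 ± 0.311 to 54.6 ± 11.4 CPM, while Stab1 (−0.43, SE 0.211) and Mrc1 (1.75, SE 0.457) did not pass. These were 2 of 14 genes, or 8 when adjusted over the list alone (camera adjusted p = 2.06e-07, and 0.0561 as an adjusted p with an estimated correlation). Among monocyte markers Fn1 and Itgal rose, 2 of 10, or 5 when adjusted over the list alone, while Ms4a4c (1.92, SE 0.526) and Ccr2 (1.88, SE 0.93) did not pass (camera adjusted p = 3.42e-05, and 0.0561 as an adjusted p with an estimated correlation). Itgal lost its call in 5 of the fits with a library left out (highest adjusted p = 0.115, without KO/KO replicate 1), and Fn1 missed the threshold in both limma-voom fits. The choroid plexus gene Clic6 had a count ratio of 545 (97.4 to 21600) and was 1 of 5 called, or 2 when adjusted over the list alone. Ttr measured 24.5 ± 36.9 CPM in KO/wt and 393 ± 400 CPM in KO/KO. In the same order Enpp2 measured 33.7 ± 52.3 and 239 ± 134 CPM, and Kl 0.78 ± 0.968 and 19 ± 13.5 CPM. Ttr, Enpp2 and Kl varied widely within each genotype and did not pass. Camera gave this list adjusted p = 0.000178, and adjusted p = 0.185 with an estimated correlation. Clic6 lost its call in 5 fits with a library left out (highest adjusted p = 0.104, without KO/wt replicate 2) and in limma-voom (0.103).

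Astrocyte, lymphoid and remaining lineage markers gave 2 calls, both decreases. The glutamate transporter gene Slc1a3 fell from 3500 ± 93.9 to 1588 ± 540 CPM (log2 fold change −1.14, SE 0.234), against the upward shift of its list, in which Ndrg2 (1.43, SE 0.406), Clu (3.0, SE 1.45) and Aldoc (2.14, SE 0.493) did not pass. Over all 6 libraries Slc1a3 had 365633 counts, against 2469 for Ndrg2, 2151 for Clu and 2161 for Aldoc. Its fall therefore cannot be read as a change in astrocytes. Of 15 astrocyte genes 4 rose and 1 fell when adjusted over the list alone, and camera gave adjusted p = 0.0173, but adjusted p = 0.185 with an estimated correlation. Slc1a3 lost its call in 4 fits with a library left out (highest adjusted p = 0.153, without KO/wt replicate 2). Il7r was the called 1 of 3 lymphocyte genes, beside Ighm (0.41, SE 0.172) and Cd79b (0.20, SE 0.415, reversed with gene length offsets). That list gave adjusted p = 0.325, or 0.388 with an estimated correlation, with its median above and its mean below 0. By edgeR's test no gene was called among 10 oligodendrocyte (Trf 0.05, Cnp 0.06, Qdpr 0.50 and Mbp 0.81 in log2 fold change, Trf and Cnp reversed with library totals alone), 8 neuronal (Camk2b 0.87, Syp 0.43, Snap25 1.87 and Camk2a −2.44), 9 endothelial and mural (Bsg 0.34, Slc2a1 0.56, Pecam1 −1.40 and Ly6a 0.78) and 3 erythroid genes (Bpgm 0.35, Car2 3.85 and Epor 1.57). At an unadjusted p under 0.05 there were 3 oligodendrocyte genes, 0 neuronal genes, 1 erythroid gene and, in endothelium, 3 higher and 1 lower. DESeq2 called 3 oligodendrocyte, 0 neuronal and 1 erythroid gene and 1 endothelial gene in each direction, limma-voom called 0 in each list, and with quality weights it called 1 oligodendrocyte gene. Adjusted over the list alone, 1 erythroid gene rose. Camera gave adjusted p = 0.0063, 0.361, 0.203 and 0.144 for these 4 lists, and adjusted p = 0.0869, 0.595, 0.283 and 0.284 with an estimated correlation. Csf3r, the only granulocyte marker tested, measured 429 ± 19.5 CPM in KO/KO and 524 ± 127 CPM in KO/wt. Csf3r and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were not called by edgeR, DESeq2 or limma-voom, and had no unadjusted p under 0.05. DESeq2 called 1 granulocyte marker lower that was not among the genes edgeR tested. Xist and Y-linked genes gave camera adjusted p = 0.904, and adjusted p = 0.908 with an estimated correlation, with median and mean of opposite sign.

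Genes around Hexb were called no more often than other genes. Of 91 tested genes within 10 Mb, 1 was called, against 460 genes elsewhere, or 1.1% against 3.72% (two-sided Fisher's exact test, p = 0.265). The called neighbour was Gfm2, a mitochondrial translation factor gene on chromosome 13 at 97137937 to 97181195, which fell from 196 ± 17.1 to 95.9 ± 11.1 CPM (log2 fold change −1.03, SE 0.161, adjusted p = 0.0177). Its exons overlap those of Hexb on the opposite strand, so reads of the 2 genes cannot be told apart there. Gfm2 lost its call in 3 of the fits with a library left out (highest adjusted p = 0.0986, without KO/wt replicate 2) and with gene length offsets (0.0586). The same exact test on called genes near Hexb gave p = 0.000232 with DESeq2's calls, again with a lower share, and p = 0.593 without KO/KO replicate 1, where the share was higher than elsewhere.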

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

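Gene length offsets, alone or with estimated correlation, and camera under most scalings were tried only after the results were seen. Against 332 genes higher and 130 lower, no low-count filter gave 712 and 436, the DESeq2 Wald test 1075 and 757, limma-voom with quality weights 202 lower, and a fold of at least 2 gave 63 lower; the cause was not tested. Leaving out 1 library gave 98 (without KO/KO replicate 1) to 243 (without KO/wt replicate 1) higher and 19 (without KO/wt replicate 2) to 120 (without KO/KO replicate 3) lower, with fewer samples in each fit. No called gene changed sign in any of these settings. Of the gene lists, 17 to 20 passed camera under other scalings, filters and omissions, 6 with an estimated correlation and 7 with an estimated correlation and gene length offsets. For called genes near Hexb, Fisher's exact test with DESeq2's calls gave p = 0.000232, and leaving out 1 library gave 0.593 (without KO/KO replicate 1, reversed) to 1 (without KO/wt replicate 2). The camera adjusted p of the unfolded protein response ran from 0.428 to 0.963 with 1 library left out and was 0.346 with gene length offsets. For 98 named genes that were called, leaving out 1 library kept the call in 357 of 588 comparisons and lost it in 231, and the other settings kept it in 848 of 879. For 56 named genes that were not called, leaving out 1 library gave 5 passes and 13 reversals of sign in 336 comparisons, and other settings 55 passes and 12 reversals in 499. With library totals alone these were Mcm3 at −0.0281, Trf at −0.0415 and Cnp at −0.0283. With limma-voom they were Mcm3 at −0.118, Cnp at −0.0105, Syp at −0.129 (−0.344 with quality weights) and Ddx3y at 0.00871. With gene length offsets they were C1qa at −0.0811, Cd79b at −0.218, Ltc4s at −0.439 and Ddx3y at 0.0731. Leaving out 1 library moved Mcm3 from −0.47 to 0.367, Cd79b from −0.167 to 0.443, Trf from −0.0202 to 0.118, Cnp from −0.204 to 0.24, Syp from −0.571 to 0.913, Bpgm from −0.568 to 0.693, Ddx3y from −0.243 to 0.084, Cst3 from −0.335 to 0.0847 and Siglech from −0.302 to 0.0932. The cause of these reversals was not tested. No paired analysis was possible because the labels give no numbers that link a KO/KO library to a KO/wt library. A sex covariate was not run, since all 6 libraries express Y-linked genes and the covariate would be constant. Depth limits genes near 0.0336 to 0.059 CPM, the level of 1 count.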

Other observations

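The gene lists described first, the genes named from them, and the tests of a library factor, of choroid plexus carry-over, of border-associated macrophages and of dilution of microglia were chosen only after the results were seen. Camera p-values of the lists described first were adjusted over those lists alone. Since those lists were picked from the same data, their p-values are descriptive and are not evidence for them.

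Of 16 genes of glycolysis 7 rose in KO/KO microglia. Tpi1 rose from 104 ± 22.7 to 287 ± 24.3 CPM (log2 fold change 1.46), Pkm from 173 ± 19 to 459 ± 83.2 CPM (1.41), Aldoa from 294 ± 69.7 to 671 ± 44.1 CPM (1.19) and Ldha from 202 ± 5.45 to 385 ± 34.8 CPM (0.93). Hk1 (−0.42), Hk2 (−0.61) and Pfkm (−1.02) lay lower and were not called. Of 20 genes of redox and metal defence 8 rose, with ferritin light chain Ftl1 from 137 ± 33.3 to 598 ± 57.4 CPM (2.12), metallothionein Mt1 (2.22), peroxiredoxin Prdx1 (1.56) and glutathione peroxidase Gpx1 (1.36), while Gclc was not called (−0.98). Of 8 annexins 4 rose, among them Anxa5 from 54.3 ± 13.8 to 381 ± 36.5 CPM (2.81) and Anxa2 from 0.695 ± 0.885 to 46.4 ± 11.7 CPM (6.01). Camera gave adjusted p = 3.08e-07 for glycolysis, 8.74e-14 for redox and metal defence and 1.14e-08 for annexins, and adjusted p = 0.0504 for each with an estimated correlation. Without KO/wt replicate 1 the log2 fold change of Anxa2 was 8.03. Calls were lost with 1 library left out for Anxa2 (highest adjusted p = 0.143, without KO/wt replicate 3), Aldoa, Ldha and Mt1 (0.0986, 0.0764 and 0.068, without KO/wt replicate 2).

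Inhibitory immune receptors moved both ways. The checkpoint receptor PD-1 (Pdcd1) rose from 17.1 ± 7.42 to 168 ± 34.5 CPM (log2 fold change 3.30), Cd72 from 7.81 ± 3.5 to 128 ± 11.4 CPM (4.03), Cd22 from 30.9 ± 9.06 to 155 ± 6.94 CPM (2.32) and Cd300lf from 2.12 ± 1.74 to 40.7 ± 6.79 CPM (4.26). Vsir, which encodes VISTA, fell from 3382 ± 223 to 1684 ± 55.6 CPM (−1.01), with Siglece (−1.60) and Ceacam1 (−1.27), so that 5 of 17 rose and 3 fell (camera adjusted p = 0.00162, and adjusted p = 0.0595 with an estimated correlation). Among 14 genes of TGF-beta reception and activation, a signal that maintains microglial identity, Eng (128 ± 3.62 to 37.2 ± 7.03 CPM, −1.78), Tgfbr1 and Itgav (−1.06 each) fell (camera adjusted p = 1.13e-07, and adjusted p = 0.0595 with an estimated correlation). Calls were lost with 1 library left out for Itgav and Siglece (highest adjusted p 0.141 and 0.0527, without KO/KO replicate 1; 0.0895 for Itgav with gene length offsets), Ceacam1 (0.194, without KO/wt replicate 2; 0.0619 with gene length offsets) and Cd300lf (0.0834, without KO/wt replicate 3), whose log2 fold change was 5.17 without KO/wt replicate 2.

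Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 split, gave as many as 462 called genes or 19 gene lists. The other splits gave at most 1 gene and 4 to 16 lists. Each of them mixes the genotypes within both groups, which widens the spread within groups, so few called genes were bound to follow. Each also keeps part of the genotype difference, so they are no fair comparison for the 462 genes or the 19 lists. With 10 splits the share cannot fall under 0.05.

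The lower homeostatic and higher disease-associated genes did not follow gene length or level. Against 10000 lists matched on exon length and CPM, the homeostatic median lay at −0.701 and the disease-associated median at 2.26 in log2 fold change relative to the matched median, and no matched list reached either. Dilution of microglia by cells that lack the homeostatic genes would lower all of them alike, but their log2 fold changes differed beyond error by Cochran's Q over the 25 genes (Q 162, df 24, p = 2.27e-22), with the standard errors of edgeR's model of all genes and a chi-square approximation that ignores correlation between genes. The intervals of 5 members lay above the list median; of these, Sparc and Siglech measured −0.16 each, and −0.15 and −0.20 with gene length offsets, but Cst3 and Ltc4s went to −0.57 and −0.44 with the offsets. The test speaks only against dilution as the sole cause, and dilution beside changes of single genes is not excluded. Nor is a gain of other macrophages that share some of these genes: medians were higher for border-associated macrophages (2.48) and monocytes (1.91), and also for choroid plexus (3.99) and astrocytes (1.43). Such dilution, that gain, an effect of genotype on microglia, and age or handling, which the labels do not give, all stay open, and no test separated them.

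Ribosomal protein and oxidative phosphorylation genes lay above lists matched on length and level, by 1.08 and 0.589, so length and level do not account for their whole shift. Mitochondrial genes were poorly matched, with a median length of 1091 bases against 1420 in the matched genes, so nothing was concluded for them. Matched lists were drawn gene by gene and leave out correlation between genes. The genes of each of these lists also moved together between libraries of 1 genotype, with an estimated correlation between genes of 0.444 for ribosomal proteins, 0.62 for oxidative phosphorylation and 0.952 for mitochondrial genes. This correlation cannot tell a library factor, such as RNA quality or amplification, from biological variation between the samples. Whether a library factor that happened to differ between the groups contributes to the rise stays open. A genotype effect on these genes was not separated from it.

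In KO/KO, 1 of 5 tested choroid plexus markers and 2 of 14 border-associated macrophage markers were called higher, with list medians of 3.99 and 2.48. The 5 choroid plexus genes moved together within each genotype (median pairwise correlation 0.725, against −0.0306 in matched gene sets, of which 0.2% were above it), so carry-over of choroid plexus RNA in differing amounts is a possible explanation of their rise. For the 14 border-associated macrophage genes the correlation was 0.108, with matched sets at −0.0111 and 11.2% of them above it, which leaves a larger share of these cells and a change within microglia both open. None of their 21 list genes belongs to another list, and of the 18 choroid plexus list genes 1 does. Their most abundant tested genes were Stab1, at 143 ± 30.5 CPM in KO/KO and 193 ± 32.7 CPM in KO/wt, and Ttr, at 393 ± 400 and 24.5 ± 36.9 CPM. No gate that would remove either cell type is given in the labels.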
